A study of Mus musculus with 8 samples.

How the data were processed

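RNA of sorted granulocyte progenitors was measured on 8 one-colour (Cy3) Agilent arrays, with 4 groups of 2 arrays. The groups were Flt3+ and Flt3- progenitors of wild-type mice and of mice labelled as Irf8 deficient. Per the labels' protocols, total RNA was extracted with a micro column kit and labelled with a low-input amplification kit. Sample groups and experiment numbers were taken from the sample titles. Per the file headers, the spot intensities were deposited as extracted by Agilent Feature Extraction 10.7.3.1 with protocol GE1_107_Sep09. The headers hold fit statistics of a background subtraction and of a spatial and a multiplicative detrending, and the values differ in level between arrays, so no scaling between arrays was applied to them. The intensities are linear brightness values. The median spot and background intensities and the flags for well above background, saturation and outliers, which are 0 or 1 per spot, were also used as deposited by the authors. The column of mean spot signal was not used here. The deposited series table holds, judged from its values, the mean processed intensity of each probe times 1 factor per array (0.672 to 1.33), on a linear scale and without centring, so that all arrays have a 75th percentile of 426.2; how the authors made it is not given in the sources used here. Its column medians were 29.9, 28.7, 26.9, 28, 28.7, 27.1, 27.5 and 27.6. It was used as an alternative only.

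Each array held 59305 non-control spots of 55681 probes. The share of spots well above background ran from 54.9 to 60.1%, no spot was saturated, 93 to 178 spots per array were left out as outliers, and the 75th percentile of the signal ran from 360 to 713. All 8 arrays lay on 1 slide and were scanned in 1 scan, so neither could be tested as a batch. Wild-type arrays lay in slide row 1 and arrays labelled Irf8KO in row 2, and Flt3+ arrays lay in columns 1 and 2 and Flt3- arrays in columns 3 and 4, so position on the slide and group cannot be told apart.

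Control and outlier spots were removed, spots of a probe were averaged, and values were taken as log2 of the processed intensity minus the 75th percentile of the array. A probe was kept if it was well above background on both arrays of at least 1 group. Probes were named through the RefSeq accession in a table of mouse genes (assembly GRCm38.p6). Of the probes 26762 were named, with 20284 symbols, 28919 were not named here, and 1628 of these carried a RefSeq accession that matched no gene. Of the named genes 5405 had several probes, and the probe with the highest mean over all 8 arrays stood for the gene, which left 14110 genes tested. Members of near-identical families (Hba, Hbb, Ear, Klra and Oas) can share hybridisation, so their values are uncertain.

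All 8 arrays were fitted with 1 mean per group in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation (4 residual degrees of freedom, prior degrees of freedom 1.76, prior SD 0.065) and Benjamini-Hochberg adjustment within each of 5 comparisons. A gene was called at an adjusted p under 0.05. The last comparison, the difference between the populations of the difference between genotypes, is an interaction. Fold changes against a group in which a gene was not well above background on any array are given as lower bounds. They set the mean of the brighter group against the mean, over arrays of the dim group, of the higher of the lowest signal among probes well above background and the signal of the probe itself. Where the signal of the probe itself was the higher, the value is no more than the fitted fold change. This was so for Sgsm1 between wild-type populations (77.0-fold) and Mmp8 between genotypes in Flt3- progenitors (14.9-fold). The dim state is that of the gene's probe. A list median with dim genes at their bound uses those values, or 0 where the bound was under 1-fold.

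The gene lists, the rule for named genes, the tests and most of the other settings tried were fixed before the data were examined. Of 21 gene lists, the 20 with at least 5 measured members were tested. They held genes of primary granules, secondary and tertiary granules, mature neutrophils, monocytes, conventional and plasmacytoid dendritic cells, MHC class II, stem and multipotent progenitors, lymphoid cells, erythroid cells and megakaryocytes, eosinophils, basophils and mast cells, G2 and M phase, S phase, interferon response, direct IRF8 targets, haematopoietic transcription factors, cytokine receptors, immediate early and heat shock genes, apoptosis and ribosome biogenesis. The list of sex-linked genes had 4 measured members and was not tested. Its median difference was 0.02 between genotypes in Flt3+ and 0.31 in Flt3- progenitors. Xist was not well above background on any array, while the Y-linked genes Ddx3y and Eif2s3y were on all 8. Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in one direction without reference to other genes, were alternatives. List counts are given over all genes tested and adjusted over the list alone.

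The rule for named genes took Irf8 and Flt3, the 8 highest and 8 lowest log2 fold changes among called genes that moved the same way in both experiments (5 and 5 for the interaction), leaving out clone and gene model names, and up to 4 members with the smallest adjusted p of each list described. If fewer genes passed, all that passed were taken. Genes outside the rule are named as chosen after their values were seen. Some genes that the rule takes are not reported here.

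Per the labels, the number in a sample's title marks one of 2 independent experiments, so equal numbers pair samples. The deviations of equal-numbered arrays from their group means correlated across genes at -0.03 to 0.12. The main comparison was made without the experiment as a block, and the block was an alternative.

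The gene test and the list test were tested on simulated data with the spread of the real genes and 200 changed genes among 14105 genes. At a log2 change of 1, the share found was 76% in the wild-type comparison of populations, 90% and 78% in the comparisons of genotypes in Flt3+ and Flt3- progenitors, 86% in the comparison of populations among arrays labelled Irf8KO and 70% for the interaction. At a log2 change of 0.25 these shares were 18, 6, 10, 22 and 0%. Calls of unchanged genes numbered 5 of 127, 7 of 132, 14 of 141, 13 of 149 and 1 of 100 calls in the same order. A shift of 0.5 in the G2 and M phase list was found in all 5 comparisons, with 0 other lists called. The genes were simulated as independent of each other. In the real data the estimated correlation ran from -0.022 for the immediate early list to 0.268 for the G2 and M phase list. The simulation therefore cannot show how often lists of correlated genes are called falsely.

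Alternatives covered the experiment block, normexp background correction, quantile and median scaling, the filter on dim probes, the choice of probe per gene, the groups in the fit, variance moderation, array weights, a minimum fold, probes without a symbol, the authors' series table and leaving out each array. Normexp was run on the median spot and background intensities with an offset of 50. The sample size of 2 per group allowed neither a test for outlying samples nor a count of other splits.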

Results

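RNA was measured in granulocyte progenitors (GPs) that had been sorted from mouse bone marrow into cells with the receptor Flt3 on their surface (Flt3+) and cells without it (Flt3-). The cells came from wild-type mice and from mice labelled as deficient for Irf8, a transcription factor of the myeloid lineages. The design gave 4 groups with 2 arrays each, 1 array per independent experiment, and 8 one-colour arrays in all. On each array 59305 spots were not controls, 54.9 to 60.1% of them lay well above background, and no spot was saturated. Arrays of one group correlated across genes at r = 0.9958 to 0.9975, and their median SD per gene was 0.039 to 0.07 log2. The number of arrays limits the precision, and nothing in the labels says how many animals stood behind each sample, so p-values measure only the spread between these samples, which may be technical. Values below are log2 signals relative to the 75th percentile of the array, and fold changes are given as log2 values with their SE, with 2 arrays per group.

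The targeted gene was examined first. The probe of Irf8 read 5.80 and 5.87 in wild-type Flt3+ GPs and 4.85 and 4.88 in wild-type Flt3- GPs. On the arrays labelled Irf8KO it read 6.67 and 6.67 in Flt3+ GPs and 5.64 and 5.53 in Flt3- GPs. Irf8 RNA was thus higher, not lower, on the arrays labelled Irf8KO, by 0.84 (SE 0.051, adjusted p = 0.000227) in Flt3+ GPs and by 0.72 (SE 0.051, adjusted p = 0.000399) in Flt3- GPs. It was the only probe that the reference table named as Irf8, and whether it lies in the deleted part of the gene is not given in the sources used here, so it does not check the labels. The genotype is therefore written below as that of arrays labelled Irf8KO, and every direction between genotypes rests on those labels. Flt3, by which the populations were sorted, read 6.21 on both wild-type Flt3+ arrays and 1.69 and 1.66 on the wild-type Flt3- arrays. On the arrays labelled Irf8KO it read 6.29 and 6.30 in Flt3+ GPs and 2.71 and 2.68 in Flt3- GPs, so Flt3 RNA followed the sort in both genotypes.

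**Figure D1:**
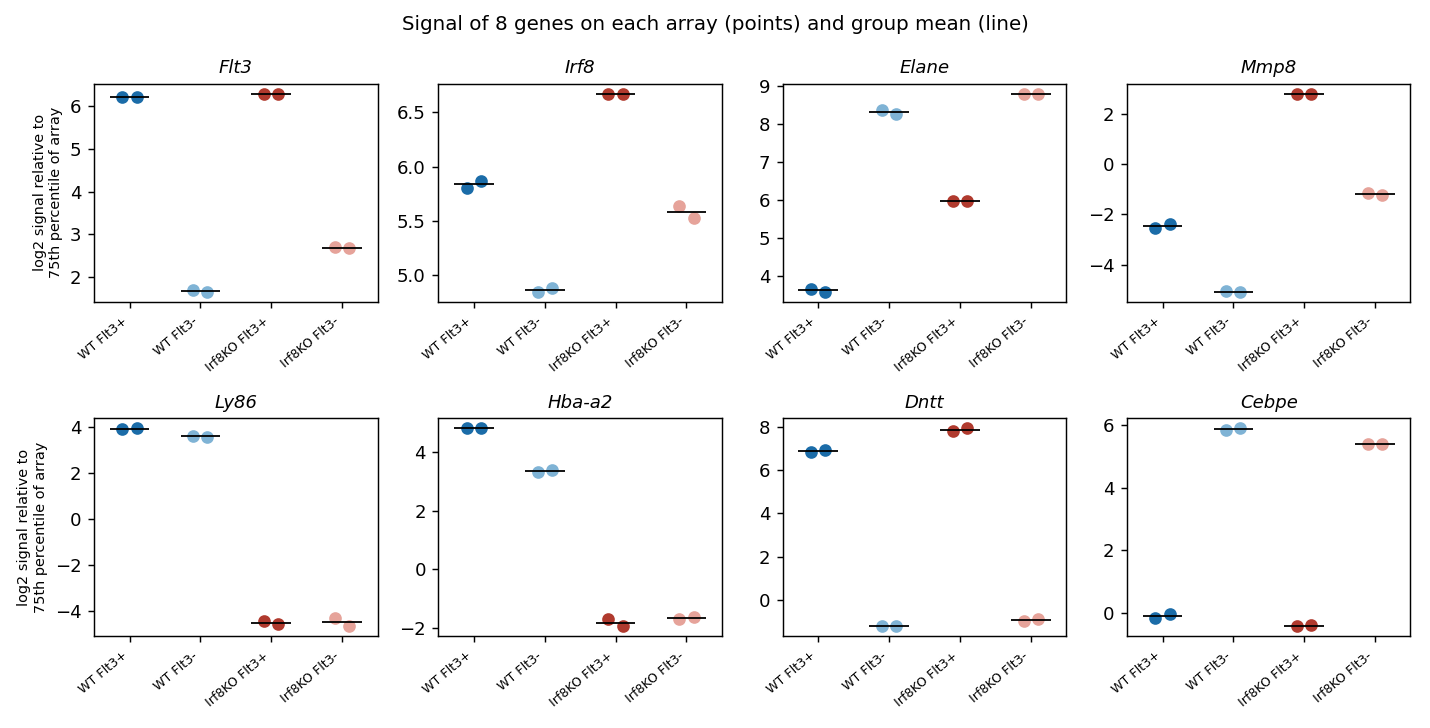
Signal of 8 genes on each of the 8 arrays (points) with the group mean (line); the vertical axis is the log2 signal relative to the 75th percentile of the array and differs between panels. Irf8 read 6.67 on both Irf8KO-labelled Flt3+ arrays, above 5.80 and 5.87 on the wild-type Flt3+ arrays. Each pair of points lies close together beside the largest difference between groups in its panel, though not beside every smaller one.

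The first comparison asked how Flt3+ and Flt3- GPs of wild-type mice differ. Flt3+ GPs carried more RNA of lymphoid, dendritic cell and stem cell genes, and less RNA of primary granule genes and of eosinophil, basophil and mast cell genes. With an estimated correlation the calls of the lymphoid (adjusted p = 0.058), conventional (adjusted p = 0.072) and plasmacytoid dendritic cell (adjusted p = 0.067), stem cell (adjusted p = 0.064) and primary granule lists (adjusted p = 0.058) were lost. Dntt, the terminal deoxynucleotidyl transferase of lymphoid precursors, was 263-fold higher in Flt3+ GPs (log2 8.04, SE 0.063), and Flt3 itself was 23.2-fold higher (4.54, SE 0.038). Cebpe, a transcription factor of granulocyte maturation, was 62.9-fold lower (-5.97, SE 0.057), and Elane, neutrophil elastase, was 25.7-fold lower (-4.68, SE 0.054). Besides Dntt, the genes with the highest ratios were Mn1 (at least 137-fold), Emp1 (127-fold), Wfdc18 (90.1-fold, with an SE of 1.1 log2), Sgsm1 (at least 77.0-fold), Rasal1 (at least 34.6-fold), Ddx4 (63.9-fold) and Wfdc17 (60.4-fold). At the other end, with Cebpe, stood Olr1 (at least 52.3-fold lower), Mogat2 (at least 112-fold lower), Chst13 (97.2-fold lower), Prom1 (74.8-fold lower), Rhou (at least 38.1-fold lower), Gda (57.5-fold lower) and Mgam (at least 30.7-fold lower). The limma adjusted p of these genes, and of Flt3, ran from 1.89e-07 to 0.0033, and that of Elane was 5.32e-07. Wfdc18 and Ddx4 were well above background on 1 of the 2 wild-type Flt3- arrays and Chst13 on 1 of the 2 wild-type Flt3+ arrays.

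Of 18 measured primary granule and early granulocyte genes, 17 fell (17 adjusted over the list alone), with a median of -2.05, or -2.04 with dim genes at their bound. Ms4a3 fell by 5.30 and Prss57 fell by 2.89 (camera adjusted p = 1.09e-08; adjusted p = 0.058 with an estimated correlation). Of 25 eosinophil, basophil and mast cell genes 21 fell (21 over the list alone), with a median of -1.33, among them Hdc, the enzyme that makes histamine (-5.33), Cpa3, a mast cell carboxypeptidase (-3.96), Il1rl1 (-4.27) and Siglecf (-2.64). This fall held with an estimated correlation (adjusted p = 1.34e-06 with the preset one, 0.039 with the estimated one). Of 28 lymphoid genes 19 rose and 5 fell (19 and 5 over the list alone, median 1.30, or 1.28 with dim genes at their bound), at adjusted p = 1.79e-05, and adjusted p = 0.058 with an estimated correlation. Ltb stood at 3.25, Lax1 was at least 19.1-fold higher and Nkg7 stood at -2.14. Of 20 conventional dendritic cell genes 16 rose and 2 fell (16 and 2 over the list alone, median 2.06, or 1.76 with dim genes at their bound), at adjusted p = 5.78e-07, and adjusted p = 0.072 with an estimated correlation. Ccr7 stood at 4.84 (well above background on 1 of the 2 Flt3- arrays), Btla at 2.29 and Kmo at 1.58. Of 17 genes of MHC class II antigen presentation 14 rose and 1 fell (14 and 1 over the list alone, median 1.37), with H2-Eb1 at 3.81, Cd74 at 3.12, H2-Ob at 2.80 and Ctss at 2.56, and the rise held with an estimated correlation (adjusted p = 1.18e-06 with the preset one, 0.039 with the estimated one). Of 29 stem and multipotent progenitor genes 22 rose and 3 fell (22 and 3 over the list alone, median 0.83), at adjusted p = 5.05e-08, and adjusted p = 0.064 with an estimated correlation. Hlf stood at 2.24 and Egfl7 at 2.23, and Prom1 was lower.

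Plasmacytoid dendritic cell genes rose in 12 and fell in 3 of 24 cases (12 and 3 over the list alone, median 0.47), at adjusted p = 0.000222, and adjusted p = 0.067 with an estimated correlation. Ccr9 stood at 4.98, Blnk at 3.95, Cox6a2 at 3.08 and Tcf4 at 1.58. Of 49 interferon-stimulated genes 35 rose and 5 fell (35 and 5 over the list alone, median 0.63), at adjusted p = 5.95e-10, and adjusted p = 0.072 with an estimated correlation. Ifi44 stood at 3.70, Rtp4 at 2.12, Oas2 at 1.90 and Ifi204 at 1.66. Of 27 immediate early and heat shock genes 20 rose and 5 fell (20 and 5 over the list alone, median 1.11), with Zfp36 at 2.67, Egr1 at 2.20, Fosb at 1.69 and Nr4a1 at 1.65, and this held with an estimated correlation (adjusted p = 7.15e-07 with the preset one, 0.039 with the estimated one). Of 35 cytokine receptor genes 20 rose and 11 fell (20 and 11 over the list alone, median 0.35), at adjusted p = 0.00185, and adjusted p = 0.29 with an estimated correlation. Il1r1 stood at 3.60 and Il18r1 at 3.41. Of 53 haematopoietic transcription factor genes 27 rose and 17 fell (27 and 17 over the list alone, median 0.24); Cebpd (-1.70) and Cebpb (-1.35) were among the lower ones (adjusted p = 0.00795; adjusted p = 0.46 with an estimated correlation). The call of this list was also lost with fry (adjusted p = 0.084). Erythroid and megakaryocyte genes rose in 12 and fell in 5 of 28 cases (12 and 5 over the list alone, median 0.16), at adjusted p = 0.00846, and adjusted p = 0.072 with an estimated correlation. Hbb-bt stood at 1.84, Plek at 1.42, Car2 at 1.29 and Itga2b at -1.94. Of 31 ribosome biogenesis genes 29 fell (29 over the list alone, median -0.40), at adjusted p = 1.66e-05, and adjusted p = 0.11 with an estimated correlation. Pno1 stood at -0.72, Nolc1 at -0.70, Heatr1 at -0.54 and Ncl at -0.47. Of 32 S phase genes 27 fell (27 over the list alone, median -0.35), at adjusted p = 0.000122, and adjusted p = 0.29 with an estimated correlation. Cdc45 stood at -0.83, Rrm2 at -0.76, Ccne1 at -0.56 and Gins2 at -0.43. The other lists were not called, namely the secondary granule, mature neutrophil, monocyte, G2 and M phase, direct IRF8 target and apoptosis genes, whose adjusted p were 0.38, 0.478, 0.791, 0.18, 0.455 and 0.252. Their medians were -0.43, -0.32, -0.17, 0.04, -0.01 and 0.06, or -0.14 and -0.26 for the first pair with dim genes at their bound. The monocyte list had a mean of -0.25 while its test pointed upwards, and the direct IRF8 target list had a mean of 0.05 with an upward test.

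Across all 14110 genes, 8727 passed the test in this comparison, 3194 higher and 5533 lower in Flt3+ GPs, and 1836 differed at least 2-fold, 1100 higher and 736 lower. The median over all genes was -0.115, and -0.013 after quantile normalization, under which 4198 genes were higher and 4122 lower. Relative to the median of -0.115, the primary granule list stood at -1.93, the eosinophil, basophil and mast cell list at -1.21, the ribosome biogenesis list at -0.28 and the S phase list at -0.23. On that scale the conventional dendritic cell list stood at 2.17, the MHC class II list at 1.48, the lymphoid list at 1.42, the immediate early list at 1.22, the stem cell list at 0.94 and the interferon list at 0.74. The plasmacytoid dendritic cell list stood at 0.59, the cytokine receptor list at 0.46, the transcription factor list at 0.35 and the erythroid list at 0.28. Camera sets each list against all other genes. Under quantile normalization the S phase list, with a median of -0.11, and the erythroid and megakaryocyte list, with a median of 0.21, were no longer called. Normexp background correction, which compresses dim signals, brought the medians of the conventional dendritic cell, lymphoid, MHC class II, and erythroid and megakaryocyte lists to 0.50, 0.48, 0.47 and 0.08.

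The second comparison set Flt3+ GPs labelled Irf8KO against wild-type Flt3+ GPs and asked how the genotypes differ in this population. Erythroid, megakaryocyte, eosinophil, basophil and mast cell genes were lower and granule genes higher on the arrays labelled Irf8KO. With an estimated correlation the calls of the secondary (adjusted p = 0.06) and primary granule lists (adjusted p = 0.082) were lost. Ly86, a secreted partner of a Toll-like receptor homologue, was 351-fold lower (log2 -8.46, SE 0.13), and Mmp8, the collagenase of neutrophil granules, was 38.1-fold higher (5.25, SE 0.064). The alpha globin genes Hba-a1 (-6.67, SE 0.12) and Hba-a2 (-6.64, SE 0.083) were 102-fold and 99.8-fold lower; these near-identical copies cannot be told apart with certainty by hybridisation. The other lowest genes were Apba1 (at least 30.9-fold lower), Ppbp, a platelet chemokine (at least 32.2-fold), Upb1 (at least 8.90-fold), Cavin2 (at least 6.84-fold) and Aif1 (at least 18.5-fold). The other highest genes were Slc13a3 (at least 11.8-fold), Slc36a2 (at least 29.5-fold), Insm1 (at least 9.96-fold), Tmem178 (15.6-fold), Abca9 (14.8-fold), Tctex1d1 (log2 3.81) and Trem3 (13.6-fold). The adjusted p of these genes ran from 1.57e-06 to 0.00404 by limma, while Flt3 RNA itself did not pass the test (0.08, SE 0.038, adjusted p = 0.156).

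Of 28 erythroid and megakaryocyte genes 23 fell and 2 rose (23 and 3 over the list alone), with a median of -1.18, or -1.19 with dim genes at their bound; Hbb-bt, a beta globin, stood at -2.91 and Pf4, platelet factor 4, at -3.58. The fall held with an estimated correlation (adjusted p = 1.22e-15 with the preset one, 0.014 with the estimated one). Of 25 eosinophil, basophil and mast cell genes 14 fell and 1 rose (15 and 2 over the list alone, median -0.81, or -0.50 with dim genes at their bound), with Ear2, an eosinophil-associated ribonuclease of a gene family with similar copies, at -4.10, Prg2, eosinophil major basic protein, at -3.57, Cpa3 at -2.68 and Gata2 at -1.40. This fall held as well (adjusted p = 8.54e-08 with the preset correlation, 0.032 with the estimated one). Of 23 secondary and tertiary granule genes 16 rose and 3 fell (16 and 3 over the list alone, median 1.78, or 0.93 with dim genes at their bound), with S100a9 at 2.00, S100a8 at 1.87 and Hp at 1.78 beside Mmp8 (adjusted p = 1.57e-05; adjusted p = 0.06 with an estimated correlation). Of 18 primary granule genes 13 rose and 1 fell (13 and 1 over the list alone, median 0.62, or 0.52 with dim genes at their bound), at adjusted p = 1.39e-07, and adjusted p = 0.082 with an estimated correlation. Elane stood at 2.34, Igsf6 at 2.07, Ms4a3 at 1.68 and Prss57 at 1.10. Of 31 G2 and M phase genes 29 rose (30 over the list alone, median 0.49), with the mitotic kinases Aurka at 0.75 and Plk1 at 0.63, Ube2c at 0.69 and Ccnb1, cyclin B1, at 0.65 (adjusted p = 1.2e-13; adjusted p = 0.14 with an estimated correlation). Of 29 stem and multipotent progenitor genes 16 fell and 3 rose (16 and 4 over the list alone, median -0.29), with Hlf at -0.95 and Prom1 higher at 1.34 (adjusted p = 0.000108; adjusted p = 0.15 with an estimated correlation). Of 17 MHC class II genes 9 fell (9 lower and 1 higher over the list alone, median -0.31), at adjusted p = 0.00121, and adjusted p = 0.082 with an estimated correlation. H2-DMb2 stood at -1.02, Cd74 at -0.92, H2-Oa at -0.43 and H2-DMb1 at -0.39. The remaining 13 tested lists were not called; the immediate early list had an adjusted p of 0.0657, the interferon list 0.315, the S phase list 0.711 and the list of genes described as direct IRF8 targets 0.532, with a median of 0.07 and a mean of -0.42.

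In all, 4089 genes passed the test, 2323 higher and 1766 lower on the arrays labelled Irf8KO, and 598 of them differed at least 2-fold, 310 higher and 288 lower. Under quantile normalization the majority turned, with 1986 higher and 2169 lower. Without Irf8KO Flt3+ replicate 1 the count was 2185 and without replicate 2 it was 2004, the fit of these groups alone called 2666, and with no filter on dim probes it was 2677. Normexp brought the secondary granule median to 0.60, the erythroid one to -0.72 and the eosinophil, basophil and mast cell one to -0.20, and all stayed called.

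The third comparison asked the same of Flt3- GPs. Again Ly86 (271-fold lower, log2 -8.08, SE 0.13), Apba1 (at least 33.0-fold lower) and the alpha globins Hba-a2 (-5.02, SE 0.083) and Hba-a1 (-4.89, SE 0.12) stood lowest on the arrays labelled Irf8KO, with Aif1 (at least 12.3-fold), Tas2r108 (at least 8.32-fold, with an SE of 0.87 log2), Rhd (at least 7.09-fold) and Hbb-b2 (at least 13.8-fold). The highest were Saa3, an acute-phase protein gene (at least 30.3-fold), Slc13a3 (at least 11.6-fold), Tmem178 (20.8-fold), Retnlg (15.9-fold), Ces2b (at least 6.23-fold), Mmp8 (at least 14.9-fold), Abca9 (14.3-fold) and Cfb, complement factor B (at least 4.38-fold). Flt3 RNA was 2.03-fold higher (1.02, SE 0.038, adjusted p = 7.7e-05). The adjusted p of the genes named so far, other than Flt3, ran from 5.26e-06 to 0.00596 by limma.

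Of 28 erythroid and megakaryocyte genes 20 fell and 2 rose (20 and 3 over the list alone, median -1.10, or -0.77 with dim genes at their bound), with Hbb-bt at -3.08 and Aqp1 at -2.19. Of 25 eosinophil, basophil and mast cell genes 18 fell (18 over the list alone, median -1.17, or -0.86 with dim genes at their bound), with Ear2 at -3.80, Ear10 at -2.94, Prg2 at -2.42 and Ear6 at -1.50. Both lists had an adjusted p of 2.38e-06 and held with an estimated correlation (adjusted p = 0.034 for each). Of 23 secondary granule genes 15 rose and 2 fell (15 and 3 over the list alone, median 0.88, or 0.65 with dim genes at their bound), with Retnlg at 3.99, S100a9 at 1.91 and Ngp at 1.52, and this rise held too (adjusted p = 3.94e-06 with the preset correlation, 0.038 with the estimated one). Of 27 immediate early and heat shock genes 20 rose and 3 fell (21 and 3 over the list alone, median 0.43), with Btg2 at 0.96, Fos at 0.93, Nr4a1 at 0.70 and Dusp1 at 0.60, which held as well (adjusted p = 1.13e-07 with the preset correlation, 0.034 with the estimated one).

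Of 32 S phase genes 31 fell (31 over the list alone, median -0.48), at adjusted p = 2.89e-11, and adjusted p = 0.14 with an estimated correlation. Ccne1 stood at -0.92, Gins2 at -0.65, E2f1 at -0.64 and Mcm2 at -0.58. Of 31 ribosome biogenesis genes 27 fell and 1 rose (28 and 1 over the list alone, median -0.40), at adjusted p = 1.13e-07, and adjusted p = 0.13 with an estimated correlation. Nolc1 stood at -0.66, Pno1 at -0.64, Gnl3 at -0.48 and Ncl at -0.46. Of 31 G2 and M phase genes 23 fell (24 over the list alone, median -0.37), at adjusted p = 3.94e-06, and adjusted p = 0.28 with an estimated correlation. Ccna2 stood at -0.61, Birc5 at -0.51, Cdca8 at -0.50 and Ccnb2 at -0.48. Interferon-stimulated genes rose in 28 and fell in 8 of 49 cases (29 and 8 over the list alone, median 0.21), at adjusted p = 3.73e-05, and adjusted p = 0.24 with an estimated correlation. Oas2 stood at 2.28, Rtp4 at 1.62, Gbp2 at 1.10 and Ddx58, an RNA sensor gene, at 0.87. Cytokine receptor genes rose in 19 and fell in 3 of 35 cases (20 and 3 over the list alone, median 0.21), at adjusted p = 1.95e-05, and adjusted p = 0.24 with an estimated correlation. Ccr2 stood at 2.10, Il10ra at 1.04 and Il1rl1 at -1.79. Of 31 monocyte and macrophage genes 17 rose and 10 fell (17 and 10 over the list alone, median 0.24, mean 0), with Gpr141 at 1.57 and F13a1 at 1.53 beside the fall of Ly86 (adjusted p = 0.00799; adjusted p = 0.29 with an estimated correlation). Of 15 mature neutrophil genes 6 rose and 1 fell (8 and 1 over the list alone, median 0.34), at adjusted p = 0.00441, and adjusted p = 0.14 with an estimated correlation. Fpr2 (well above background on 1 of the 2 arrays labelled Irf8KO) was at least 1.94-fold higher, Trem3 stood at 0.71 and Wfdc21 at -1.28. Of 53 transcription factor genes 22 rose and 12 fell (23 and 12 over the list alone, median 0.09, or 0.08 with dim genes at their bound), at adjusted p = 0.0106, and adjusted p = 0.44 with an estimated correlation. Gata2 stood at -1.17 and Ikzf2 at -0.78. Of 18 primary granule genes 7 rose and 2 fell (7 and 3 over the list alone, median 0.14), with Mgst2 at 1.08, Gstm1 at 0.77, Igsf6 at 0.71 and Elane at 0.49 (adjusted p = 0.0342; adjusted p = 0.29 with an estimated correlation), a call that was lost under normexp, under quantile normalization and without Irf8KO Flt3- replicate 1, with medians of 0.15, 0.06 and 0.12. The lists not called were those of conventional and plasmacytoid dendritic cells, MHC class II, stem cells, lymphoid cells, direct IRF8 targets and apoptosis, with adjusted p of 0.203, 0.743, 0.202, 0.222, 0.377, 0.0675 and 0.529. The direct IRF8 target list had a median of 0.19 and a mean of -0.23, and the MHC class II list a median of -0.31, or -0.19 with dim genes at their bound.

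In all, 6158 genes passed the test, 2322 higher and 3836 lower, and 512 of them differed at least 2-fold, 249 higher and 263 lower. With quantile normalization the split was 2807 higher and 3238 lower. Without wild-type Flt3- replicate 2 the count was 4051. In the simulated data for this comparison 14 of 141 calls were of unchanged genes, a larger share than the threshold of 0.05 allows, so the count may be too high. Normexp brought the medians of the secondary granule, erythroid, and eosinophil, basophil and mast cell lists to 0.46, -0.49 and -0.39, and all stayed called.

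**Figure D2:**
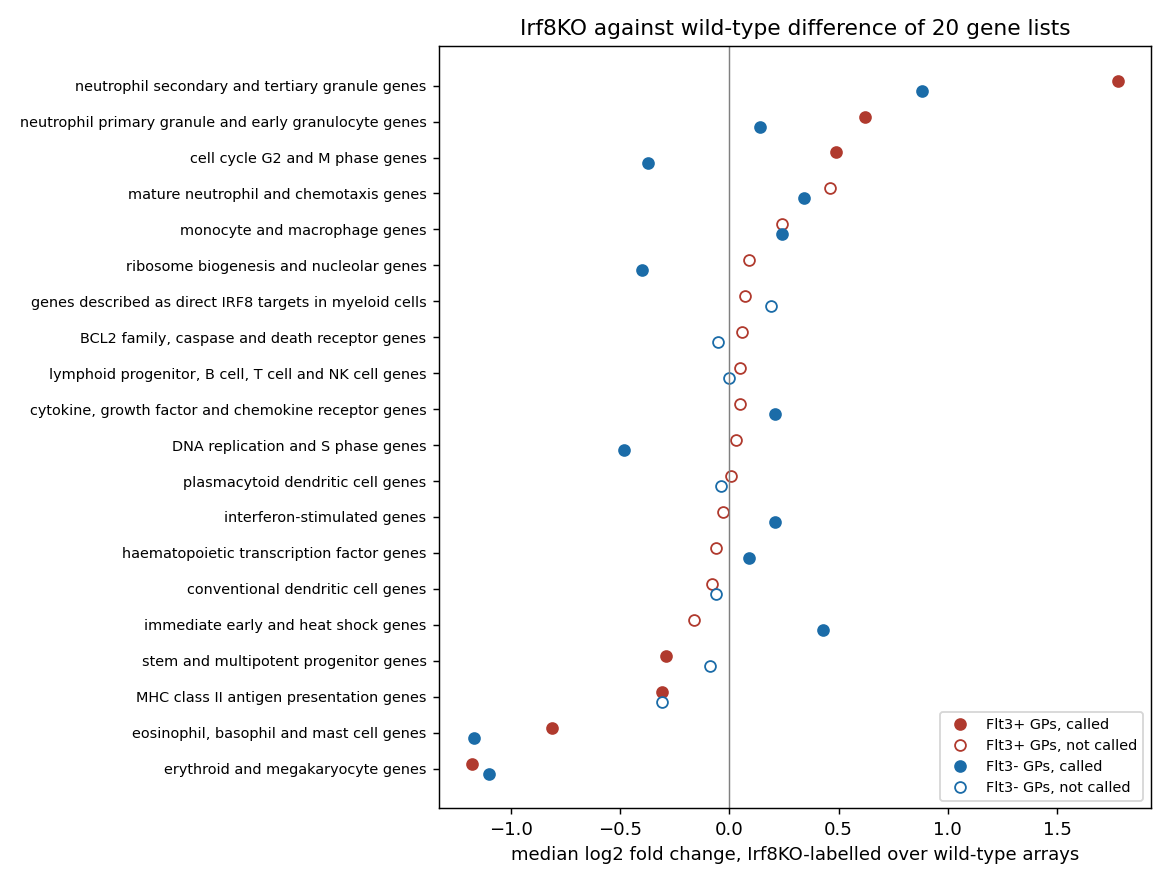
Median log2 fold change of 20 gene lists between arrays labelled Irf8KO and wild-type arrays (horizontal axis), in Flt3+ GPs (red) and Flt3- GPs (blue), from fitted values without bounds for dim genes; filled points passed camera with the preset correlation. The G2 and M phase list stood at 0.49 in Flt3+ and at -0.37 in Flt3- GPs, and the erythroid and megakaryocyte list at -1.18 and -1.10.

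Changes between genotypes overlapped in both populations, in comparisons that share no arrays. They do share 1 estimate of the spread per gene, and the genotypes lay in the same slide rows in both. The counts given for independent lists do not allow for this. Genes called in the same direction in both numbered 1866, of which 913 were higher and 953 lower on the arrays labelled Irf8KO, where independent lists would share 382 and 480, and 619 genes were called in opposite directions, where independent lists would give 922. At a minimum of 2-fold, 113 were higher and 120 lower in both, against 5.5 and 5.4 for independent lists, and 12 were opposite. Across genes, which are not independent replicates, the fold changes correlated at r = 0.51 (Spearman's rho 0.32, covariance 0.133). Without Irf8KO Flt3+ replicate 1 the genes called in the same direction numbered 1182, and without replicate 2 they numbered 1145.

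**Figure D3:**
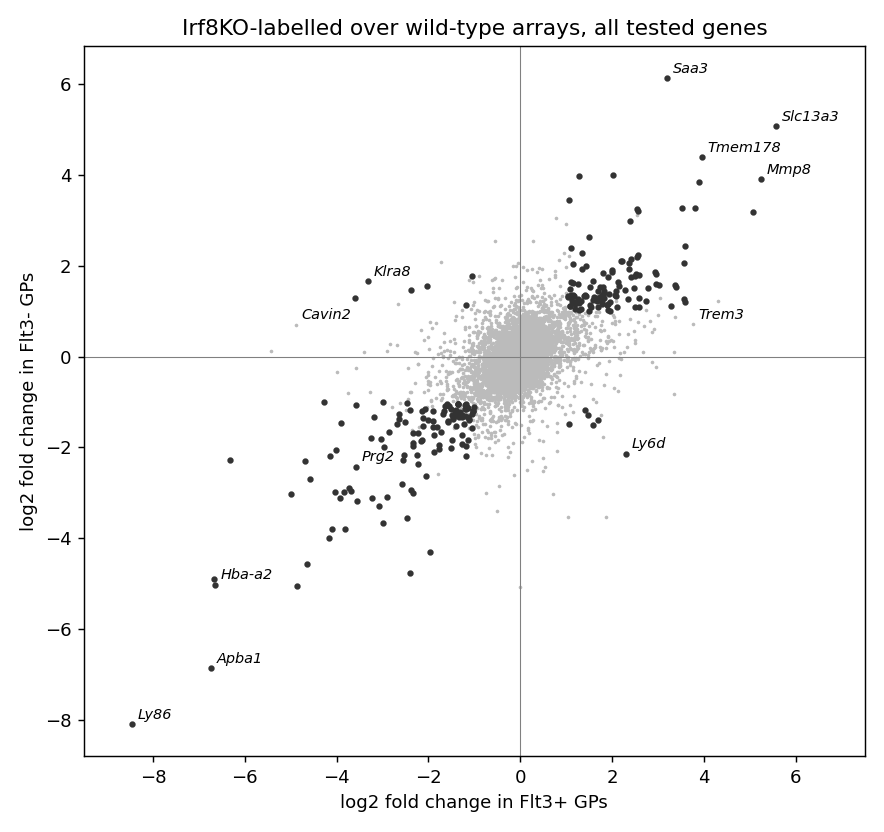
Log2 fold change of each of the 14110 tested genes between arrays labelled Irf8KO and wild-type arrays in Flt3+ GPs (horizontal axis) and Flt3- GPs (vertical axis); dark points changed at least 2-fold with a call in both populations, in either direction. Ly86 lies at -8.46 and -8.08, and Ly6d and Klra8 lie in opposite corners.

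The fourth comparison set Flt3+ against Flt3- GPs among the arrays labelled Irf8KO. Il7r, the interleukin receptor of early lymphoid cells (at least 113-fold higher), Dntt (429-fold, log2 8.75, SE 0.063), Rag1 (at least 75.3-fold), Ly6d (202-fold), Epha2 (at least 36.6-fold), Emp1 (99.3-fold), Cmah (90.1-fold) and Nsg2 (at least 30.6-fold) stood highest in Flt3+ GPs, and Flt3 was 12.1-fold higher (3.60, SE 0.038). Lowest were Olr1 (at least 57.8-fold lower), Vcam1 (at least 30.4-fold), Mogat2 (69.4-fold), Cebpe (56.7-fold, log2 -5.83, SE 0.057), Gata1 (36.1-fold), Cpa3 (35.2-fold), Klra8 (at least 9.67-fold) and Nrg1 (at least 25.3-fold). Irf8 was 2.12-fold higher in Flt3+ GPs (1.09, SE 0.051), beside 1.96-fold in wild type (0.97, SE 0.051), and the difference between genotypes did not pass the test (adjusted p = 0.291). The adjusted p of these genes ran from 3.12e-07 to 9.34e-05 by limma. In the dimmer population Ly6d and Cmah (Flt3-), and Mogat2 and Gata1 (Flt3+), were well above background on 1 of the 2 arrays.

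Of 18 primary granule genes 17 fell (17 over the list alone, median -1.86), with Ms4a3 at -3.43, Gstm1 at -3.19 and Nkg7 at -2.00. Of 25 eosinophil, basophil and mast cell genes 22 fell (22 over the list alone, median -1.45, or -1.44 with dim genes at their bound), with Hdc at -4.45, Prg2 at -3.15 and Siglecf at -2.62. Of 17 MHC class II genes 13 rose and 2 fell (13 and 2 over the list alone, median 0.94, or 0.89 with dim genes at their bound), with Ctss at 3.76, H2-Eb1 at 3.60 and Cd74 at 2.58. Of 27 immediate early genes 16 rose and 2 fell (16 and 2 over the list alone, median 0.23), with Klf2 at 2.33, Nr4a1 at 1.75, Dusp2 at 0.98 and Gadd45b at -1.77. These 4 lists had adjusted p of 3.33e-11, 1.34e-10, 2.63e-05 and 7.13e-05, and all held with an estimated correlation (adjusted p = 0.047, 0.034, 0.047 and 0.047). Of 31 G2 and M phase genes 30 rose and 1 fell (30 and 1 over the list alone, median 0.83), at adjusted p = 2.36e-14, and adjusted p = 0.13 with an estimated correlation. Kif23 stood at 1.38, Ccnb1 at 1.18, Plk1 at 1.09 and Bub1b at 0.90. Of 32 S phase genes 17 rose and 1 fell (18 and 1 over the list alone, median 0.18), at adjusted p = 5.11e-05, and adjusted p = 0.26 with an estimated correlation. Mcm10 stood at 0.46, Pcna at 0.29 and Pole at 0.55, whose probes disagree, since their mean gave -0.41. Conventional dendritic cell genes rose in 13 and fell in 2 of 20 cases (13 and 2 over the list alone, median 1, or 0.68 with dim genes at their bound), at adjusted p = 0.000135, and adjusted p = 0.15 with an estimated correlation. Itgax stood at 3.66. Plasmacytoid dendritic cell genes rose in 12 and fell in 2 of 24 cases (13 and 2 over the list alone, median 0.32), at adjusted p = 0.00262, and adjusted p = 0.13 with an estimated correlation. Blnk stood at 5.83 and Mzb1 at 4.72. Of 29 stem and progenitor genes 21 rose and 5 fell (21 and 5 over the list alone, median 0.71), at adjusted p = 3.28e-05, and adjusted p = 0.13 with an estimated correlation. Mn1 stood at 6.36 and Egfl7 at 2.94. Lymphoid genes rose in 14 and fell in 8 of 28 cases (15 and 9 over the list alone, median 0.52), at adjusted p = 0.0191, and adjusted p = 0.15 with an estimated correlation. Vpreb3 stood at 4.22 and Lax1 was at least 15.8-fold higher. The call of the lymphoid list was also lost when all arrays had to be well above background (median 0.47). Interferon-stimulated genes rose in 31 and fell in 5 of 49 cases (32 and 5 over the list alone, median 0.30), at adjusted p = 2.07e-06, and adjusted p = 0.15 with an estimated correlation. Ifi44 stood at 2.90, Rtp4 at 1.65, Ifi204 at 1.45 and Xaf1 at 0.84. The other lists were not called, with adjusted p of 0.136 for the secondary granule, mature neutrophil, transcription factor and apoptosis lists, 0.165 for ribosome biogenesis, 0.261 for cytokine receptors, 0.278 for monocytes, 0.32 for direct IRF8 targets and 0.525 for erythroid and megakaryocyte genes. Normexp brought the medians of the conventional dendritic cell, eosinophil, basophil and mast cell, MHC class II and lymphoid lists to 0.48, -0.75, 0.51 and 0.17.

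In all, 6459 genes passed the test in this comparison, 3123 higher and 3336 lower, and 1473 differed at least 2-fold, 859 higher and 614 lower. Under quantile normalization the majority turned, with 3796 higher and 3083 lower. In simulated data 13 of 149 calls were of unchanged genes, again in a single simulated set. Whether this count is too high cannot be told from it either. Genes called in the same direction between Flt3+ and Flt3- GPs in both genotypes numbered 4869, with 2123 higher and 2746 lower in Flt3+ GPs, where independent lists would share 707 and 1308, and 390 were opposite. At a minimum of 2-fold, 704 were higher and 489 lower in both genotypes and 3 were opposite. Across genes the fold changes correlated at r = 0.83 (rho 0.68, covariance 0.617). The comparisons of populations likewise share 1 estimate of the spread per gene and the same slide columns, which the counts for independent lists do not allow for.

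The last comparison tested whether the difference between genotypes itself differed between the populations, as the change in Flt3+ GPs minus the change in Flt3- GPs. Of 31 G2 and M phase genes 30 had a positive difference (31 over the list alone, median 0.83), at adjusted p = 1.03e-14, and adjusted p = 0.15 with an estimated correlation. Ccnb1 stood at 1.08, Plk1 at 1.05, Cdca8 at 0.84 and Ccnb2 at 0.83. Of 32 S phase genes 30 had a positive difference (30 over the list alone, median 0.53), at adjusted p = 1.38e-11, and adjusted p = 0.15 with an estimated correlation. Rrm2 stood at 0.96, Ccne1 at 0.90 and Mcm10 at 0.88. Ribosome biogenesis genes had a positive difference in 26 of 31 cases (29 over the list alone, median 0.52), at adjusted p = 8.37e-09, and adjusted p = 0.15 with an estimated correlation. Nolc1 stood at 0.76 and Ncl at 0.62. Primary granule genes had a positive difference in 9 and a negative one in 1 of 18 cases (10 and 1 over the list alone, median 0.37), at adjusted p = 0.000634, and adjusted p = 0.18 with an estimated correlation. Ms4a3 stood at 1.87 and Elane at 1.85. Immediate early genes had a negative difference in 15 and a positive one in 3 of 27 cases (16 and 3 over the list alone, median -0.54), at adjusted p = 4.55e-07, and adjusted p = 0.08 with an estimated correlation. Fosb stood at -1.58, Btg2 at -1.23, Fos at -1.22 and Dusp1 at -1.21. Interferon-stimulated genes had a negative difference in 24 and a positive one in 5 of 49 cases (29 and 5 over the list alone, median -0.35), at adjusted p = 9.99e-09, and adjusted p = 0.15 with an estimated correlation. Oas2 stood at -0.94, Oasl2 at -0.79 and Ifitm3 at -0.68. The Oas genes are a family of similar copies, so their values are uncertain.

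The other lists with a called difference were negative by the test. Of 28 erythroid and megakaryocyte genes 11 had a negative and 4 a positive difference (12 and 4 over the list alone, median -0.17), with Pf4 at -2.52 and Vwf at -1.65. Of 35 cytokine receptor genes 13 were negative and 4 positive (14 and 4 over the list alone, median -0.17), with Il10ra at -1.17 and Cx3cr1 at 2.15. Of 29 stem and progenitor genes 10 were negative and 5 positive (13 and 5 over the list alone, median -0.19), with Ly6a at -0.88. Of 20 conventional dendritic cell genes 6 were negative and 2 positive (6 and 2 over the list alone, median -0.15), with Clec9a at -3.63, a fitted value for a gene well above background only on the wild-type Flt3+ arrays, and Relb at -1.03. Of 25 direct IRF8 target genes 7 were negative and 2 positive (7 and 2 over the list alone, median -0.07), with Ccl5 at -1.68 and Ctss at 1.19. Of 53 transcription factor genes 17 were negative and 5 positive (19 and 7 over the list alone), with a median of 0 and a mean of -0.20, among them Jun at -0.99. Their adjusted p were 0.000699, 0.000699, 0.00485, 0.00758, 0.0174 and 0.00766, in that order, and none of these was called with an estimated correlation (adjusted p = 0.15, 0.27, 0.25, 0.27, 0.25 and 0.44). The most positive differences of single genes were those of Kng2 (5.42, SE 0.88), Tas2r108 (5.06, SE 1.2), Lbhd2 (4.58, SE 0.93), Ly6d (4.45, SE 0.33) and Esm1 (4.18, SE 0.48). The most negative were those of Cavin2 (-5.59, SE 0.11), Klra8 (-4.97, SE 0.11), Cd2 (-4.87, SE 0.16), Ppbp (-4.06, SE 0.27) and Klra4 (-3.86, SE 0.61). Each of these 10 genes was not well above background on at least 1 array, so the sizes are fitted values and no bounds, and their limma adjusted p ran from 8.28e-05 to 0.0281. Tas2r108 and Lbhd2 were well above background only on the wild-type Flt3- arrays. The call of Tas2r108 was lost with no filter on dim probes and with array weights (5.06 in both), under normexp (1.90), without wild-type Flt3+ replicates 1 and 2 (5.24 and 4.87), without Irf8KO Flt3+ replicates 1 and 2 (5.12 and 4.99) and without Irf8KO Flt3- replicates 1 and 2 (5.16 and 4.95). That of Lbhd2 was lost without wild-type Flt3- replicate 2 (4.21), Irf8KO Flt3+ replicate 1 (4.02) and Irf8KO Flt3- replicate 1 (4.25). The difference of Flt3 was -0.94 (SE 0.054, adjusted p = 0.000783) and that of Irf8 0.11 (SE 0.072, adjusted p = 0.291).

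In all, 4357 genes had a called difference, 3023 positive and 1334 negative, and 431 of them were at least 2-fold, 194 positive and 237 negative. Under quantile normalization 1976 were positive and 1865 negative. The lists without a called difference were the secondary granule, mature neutrophil, monocyte, plasmacytoid dendritic cell, MHC class II, lymphoid, eosinophil, basophil and mast cell, and apoptosis lists, with adjusted p of 0.329, 0.869, 0.941, 0.382, 0.152, 0.697, 0.651 and 0.941. Without wild-type Flt3- replicates 1 and 2 in turn the count was 2587 and 2553, without Irf8KO Flt3+ replicates 1 and 2 it was 2900 and 2518, and with no filter on dim probes it was 2725.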

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

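The tests of explanations for the last 3 patterns were chosen only after the results were seen, while the interaction tests were planned. The difference between genotypes differed between Flt3+ and Flt3- progenitors, by the limma interaction test, for 4357 of the 14110 genes tested and for 132 of the 170 named genes, which the rule takes for large or clear changes. Of the 69 whose difference was at least 2-fold, those reported are given here. Values are the log2 change in Flt3+ minus that in Flt3- progenitors, and fitted values for genes dim on some arrays. Il7r, Rag1, Epha2 and Nsg2 were dim on every Flt3- array, Ppbp and Upb1 on every array labelled Irf8KO, and Saa3 on every wild-type array. Clec9a, Cfb, Insm1, Tas2r108 and Lbhd2 were well above background in a single group only. Part of each of these differences thus rests on dim signals. Negative values were those of Cavin2 (-5.59), Klra8 (-4.97), Cd2 (-4.87), Ppbp (-4.06), Klra4 (-3.86), Clec9a (-3.63), Vcam1 (-3.27), Saa3 (-2.92), Ces2b (-2.70), Pf4 (-2.52) and Cfb (-2.39). Further negative values were those of Upb1 (-1.97), Retnlg (-1.97), Hba-a1 (-1.77), Ccl5 (-1.68), Vwf (-1.65), Hba-a2 (-1.62), Nrg1 (-1.60), Zfp36 (-1.60), Sgsm1 (-1.58), Fosb (-1.58) and Egr1 (-1.48). Smaller ones were those of Ltb (-1.26), Naip2 (-1.24), Btg2 (-1.23), Gata1 (-1.22), Fos (-1.22), Dusp1 (-1.21), Cpa3 (-1.18), Il10ra (-1.17), Prg2 (-1.15) and Relb (-1.03). Positive values were those of Aqp1 (1.00), Prtn3 (1.01), Mogat2 (1.05), Plk1 (1.05), Ccnb1 (1.08), Ctss (1.19), Prom1 (1.23), Mmp8 (1.35), Igsf6 (1.36), Cox6a2 (1.42), S100a8 (1.52) and Hp (1.60). Larger ones were those of Gpr141 (1.81), Elane (1.85), Nsg2 (1.87), Ms4a3 (1.87), Blnk (1.89), Slc36a2 (1.90), Gda (2.04), Cx3cr1 (2.15), Chst13 (2.25), Rag1 (2.25), Rhou (2.30) and Rhd (2.34), and Epha2 (2.45), Mzb1 (2.52), Vpreb3 (2.56), Wfdc21 (2.75), Trem3 (3.06), Insm1 (3.09), Il7r (3.09), Esm1 (4.18), Ly6d (4.45), Lbhd2 (4.58), Tas2r108 (5.06) and Kng2 (5.42).

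Among the gene lists the same test, by camera with the preset correlation, gave a difference for the lists of primary granules (median 0.37), conventional dendritic cells (-0.15), stem cells (-0.19), erythroid cells and megakaryocytes (-0.17), G2 and M phase (0.83), S phase (0.53), interferon response (-0.35), direct IRF8 targets (-0.07), transcription factors (0), cytokine receptors (-0.17), immediate early genes (-0.54) and ribosome biogenesis (0.52). None of these was called with an estimated correlation. Among 14154 probes without a gene symbol, which the comparisons did not use, 94 changed at least 2-fold in the same direction between genotypes in both populations, 79 higher and 15 lower on the arrays labelled Irf8KO.

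Irf8 RNA was higher on the arrays labelled Irf8KO in both populations. Array scaling as the cause was argued against, since the lowest difference over 5 background corrections or scalings was 0.67. Exchanged genotype labels stay open, since genes described as direct IRF8 targets went both ways. Their median was 0.07 in Flt3+ and 0.19 in Flt3- progenitors, and their mean -0.42 and -0.23. Of 25 members, 5 were called higher and 7 lower in Flt3+ progenitors, and 11 higher and 7 lower in Flt3- progenitors. The member Ly86 stood at -8.46 and -8.08. Transcripts that keep the probe's target while lacking another part of Irf8 could also give the higher Irf8 value. With 1 probe named as Irf8 this was not decided. A biological change of Irf8 RNA in mutant cells was not tested.

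Erythroid and megakaryocyte RNA and eosinophil, basophil and mast cell RNA were lower on the arrays labelled Irf8KO in both populations. Of the 34 members lower in both populations 1 lay within 20 Mb of Irf8. A segment of another strain there could thus hold few of these genes. The choice of lists fixed these positions in advance. An effect of such a segment on genes elsewhere was not tested, so this explanation stays open. Array scaling was argued against, since the list median closest to 0 was -0.74 over all scalings. Under normexp that median was -0.20, with every call kept. The normexp offset of 50 shrinks differences of dim genes whatever their cause, so this does not decide on background correction, which stays open. A single source of red cell RNA with fixed composition could account for part of it; the log2 change of Hba-a2 minus that of Hbb-bt was -3.74 in Flt3+ and -1.94 in Flt3- progenitors, but beta globin genes differed among each other, with Hbb-b2 at -4.64 and Hbb-bt at -2.91 in Flt3+ progenitors, so that differences of strain or probe keep this open. A biological difference between genotypes stays open as untested.

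Genes of G2 and M phase moved apart, higher on the arrays labelled Irf8KO in Flt3+ and lower in Flt3- progenitors. With an estimated correlation the list was not called in Flt3+ (adjusted p = 0.14), in Flt3- (adjusted p = 0.28) or for the interaction (adjusted p = 0.15). Array scaling was argued against, with a lowest median difference of 0.70 over 5 background corrections or scalings, and so was a single array, with a lowest median of 0.75 when 1 array was left out. Position on the slide cannot be told apart from the groups, since 0 groups had arrays in more than 1 slide row. A biological difference between genotypes that depends on the population stays open as untested.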

How the results depend on the processing

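The test against a 1.2-fold change, the 2-fold minimum with median scaling, the inclusion of probes without a symbol and normexp on median in place of mean spot signal, which was not used here, were chosen after seeing the data. With an estimated correlation the lists called fell to 3 in the wild-type comparison of populations and 4 among arrays labelled Irf8KO. They fell to 2 and 4 in the comparisons of genotypes in Flt3+ and Flt3- progenitors and to 0 for the interaction. The estimate was -0.014 for the erythroid and megakaryocyte list and -0.022 for the immediate early list, below the preset 0.01. Both lost their interaction call all the same. For genotype in Flt3+ progenitors the MHC class II (0.003) and secondary granule lists (0.007), also below the preset, lost their calls too. A higher correlation between genes thus did not cause those losses, and what did was not tested. A call lost with an estimated correlation is therefore not by itself a sign of correlated genes. Fry called 15 lists for genotype in Flt3+ progenitors and 18 for populations among arrays labelled Irf8KO; the cause was not tested. In the order wild-type populations, genotype in Flt3+, genotype in Flt3-, populations among arrays labelled Irf8KO and interaction, a minimum of 2-fold left 1836, 598, 512, 1473 and 431 genes, and 1835, 600, 518, 1474 and 434 with median scaling. The test against a 1.2-fold change called 4581, 1141, 1729, 3104 and 972. Genes called in the same direction between populations in both genotypes numbered 1193 at 2-fold, 1193 with median scaling as well and 2395 against 1.2-fold, and between genotypes in both populations 233, 237 and 543, fewer by construction. With no filter on dim probes the count was 2677 for genotype in Flt3+, 2725 for the interaction and 1226 for shared genotype calls, and with only the compared groups in the fit it was 2666 for genotype in Flt3+; the cause was not tested. No such fit exists for the interaction, and slide and scan as a block were not run, since there was 1 of each.

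With experiments paired as a block, the counts were 8781, 4008, 6203, 6553 and 4408 genes and 14, 7, 13, 11 and 12 lists, with 4903 shared population calls and 1839 shared genotype calls, and no call of a named gene or list changed. Leaving out 1 array at a time, with a lone array assumed to vary like the other groups, gave 7188 to 8552 genes for wild-type populations, 2004 (without Irf8KO Flt3+ replicate 2; 2185 without replicate 1) to 3676 for genotype in Flt3+, 4051 (without wild-type Flt3- replicate 2) to 6438 for genotype in Flt3-, 4936 to 6818 among arrays labelled Irf8KO and 2518 to 4413 for the interaction. The low interaction counts were 2587 and 2553 without wild-type Flt3- replicates 1 and 2 and 2900 and 2518 without Irf8KO Flt3+ replicates 1 and 2. Shared population calls ran from 3894 to 4860 and shared genotype calls from 1145 to 1608, with 1182 and 1145 without Irf8KO Flt3+ replicates 1 and 2. Lists called ran from 14 to 14, 7 to 8, 12 to 14, 11 to 11 and 12 to 12.

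Of 279 named-gene results, 3 changed sign. Under quantile normalization Flt3 between genotypes in Flt3+ progenitors went from 0.08 to -0.03 and the interaction of Irf8 from 0.11 to -0.13, neither called, and Pole among arrays labelled Irf8KO went from 0.55 to -0.41 with the mean of its probes, which disagree; the cause of the first pair was not tested. The 2-fold minimum ended 68 named-gene calls, and 60 named-gene results had no value when all arrays had to be well above background, both by construction. Of 57 called list results, 44 were lost with an estimated correlation, 3 under quantile normalization and 1 each under normexp, fry, the strictest filter and leaving out Irf8KO Flt3- replicate 1. Normexp shrank 14 of the 54 list medians of at least 0.1 by over 1.5 times. It also replaced the processed intensity by median spot and background intensities. Whether the lists that shrank were those with the dimmest genes was not tested.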

Other observations

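Klra8, Klra4, Cd2, Hba-a1, Hba-a2, Hbb-b2 and Hbb-bt were named by the fixed rule, and Xcl1, Il2rb, Klra7 and Hbb-bs were chosen after their values were seen. Il2rb, an interleukin receptor chain, was well above background on all 8 arrays and on those labelled Irf8KO stood at -0.89 relative to wild type in Flt3+ progenitors and at 1.76 in Flt3- progenitors (limma interaction adjusted p = 0.000818). The next genes were not well above background on either Flt3+ array labelled Irf8KO, so their change in that population is a lower bound. Klra8, a receptor gene of natural killer cells, was at least 2.86-fold lower there and stood at 1.66 in Flt3- progenitors (interaction adjusted p = 8.28e-05). Cd2, a surface protein of T and natural killer cells, was at least 2.87-fold lower and stood at 1.29 (interaction adjusted p = 0.000183), and Klra4 was at least 2.38-fold lower and stood at 1.47 (interaction adjusted p = 0.00811). The chemokine gene Xcl1 was at least 1.63-fold lower and stood at 1.54, with 1 of the 2 wild-type Flt3- arrays well above background (interaction adjusted p = 0.00325). Klra7 did not pass the test in Flt3+ progenitors (adjusted p = 0.0918) and stood at 2.08 in Flt3- progenitors (adjusted p = 0.0412), with 1 of the 2 arrays of each wild-type group well above background. The Klra genes are a family of similar copies, which makes their values uncertain.

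The log2 change from Flt3- to Flt3+ in wild type was 1.43 for Hba-a1, 1.45 for Hba-a2 and 1.84 for Hbb-bt, which were well above background on all 8 arrays. Among the arrays labelled Irf8KO it was -0.34 and -0.17 for Hba-a1 and Hba-a2, neither of which passed the test (limma adjusted p = 0.0597 and 0.161), and 2.02 for Hbb-bt (adjusted p = 2.22e-06). The interaction was -1.77 (adjusted p = 0.00228), -1.62 (adjusted p = 0.00144) and 0.18 (adjusted p = 0.0816) in the same order. Hba-a1 and Hba-a2 thus differed from Hbb-bt. Since Hbb-bt was the only beta globin gene compared in both genotypes on signals well above background, these values do not set alpha against beta globin as such. The change in wild type was 1.72 for Hbb-b2 (adjusted p = 0.0369) and 1.66 for Hbb-bs. Among the arrays labelled Irf8KO the changes between populations of Hbb-b2 (1.65) and Hbb-bs (-0.30) are fitted values only. Neither gene was well above background on the Flt3- arrays there, so these changes are not exact. Globin genes have near-identical copies, and the differences between these genes were not tested. Of the genes tested within 5 Mb and 10 Mb of Irf8 in the reference table, 0 of 93 and 0 of 130 were called by limma with at least a 2-fold change in the same direction in both populations. Within 20 Mb it was 2 of 226, of 233 such genes in all.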
